A study of Arabidopsis thaliana with 8 samples.

How the data were processed

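The data are 8 Agilent arrays of 2 colours each, with 16 channels in total. Per the labels, WT, apx1, cat2 and apx1/cat2 plants grown at 100 µmol m-2 s-1 were moved to 1000 µmol m-2 s-1 for 0 or 1 h, and each array compares 1 h with 0 h of one genotype. RNA came from middle-aged leaves of 25 plants and 1 µg was labelled. Each genotype has 2 replicates, which the labels describe as independent experiments. The 1 h sample carries Cy5 in replicate 1 and Cy3 in replicate 2, so dye orientation, replicate number and scan session are one and the same split. The plants were at one growth stage but differed in age, 21 days for WT, 25 for apx1, 27.5 for cat2 and 32 for apx1/cat2.

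Per the file headers, the authors scanned each array with Agilent Feature Extraction 8.1.1.1, which gave a mean intensity and a background intensity per spot and channel. The same program made processed intensities by spatial detrending followed by linear and lowess dye normalization. The deposited series values are log10 ratios of 1 h over 0 h, centred within each array, with a median of 0 in all 8 columns, and they were turned to log2 by the known factor for one alternative. They equal the log10 ratio of the scanner file in replicate 1 and its negative in replicate 2. The raw ratios of dye-swapped arrays correlate negatively, which settled the direction.

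The values used here start from the mean intensities per the file headers. Background was handled by normexp with an offset of 50, dye bias by loess within each array, and arrays were brought to one scale by Aquantile, after which all values are log2. Of 39941 spots, 26200 probe spots name 1 locus, 234 name several loci, 8821 lie in genome intervals, 2430 are other transcripts and 2256 are controls. The array names 25438 loci, and 25230 of them were matched in the reference table. A locus was kept if it was well above background in at least 2 of 16 channels, and its brightest probe stood for it, which left 24529 loci. Spots with several loci, other transcripts and controls were not used here.

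Tests were run in limma 3.58.1 under R 4.3.3, with the data.table package (version 1.17.8) and statmod 1.5.0, and figures were drawn with matplotlib 3.10.9 under Python 3.11.15. A linear model with one coefficient per genotype and a dye and replicate term was fitted to the ratios for light responses and to the channel values at 0 h and at 1 h for genotype differences. The fits have 3 residual degrees of freedom, and the empirical Bayes step added 2.8 for responses, 3.88 at 0 h and 4.38 at 1 h. p values were adjusted by Benjamini-Hochberg over all loci, with a threshold of 0.05. A difference in response and the departure from additivity were tested as contrasts of these coefficients. Where one group lies below background or is saturated, the fold is given as at least the ratio to the background limit or to the saturated value.

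The replicate pairing was checked as the correlation across genes of the replicate deviations of each pair of genotypes. For the ratios it was 0.575 for WT and apx1, 0.446 for WT and cat2 and 0.442 for apx1 and cat2, but -0.141, -0.208 and 0.0396 for apx1/cat2 with WT, apx1 and cat2. The term was kept as planned, and results without it are given in the closing section. Replicate arrays correlated across genes with r = 0.853 in WT, 0.791 in apx1, 0.905 in cat2 and 0.711 in apx1/cat2.

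Named genes follow one rule, fixed before the data were examined, as were the gene lists, the comparisons and the alternative settings. The rule names the targeted genes, the 10 largest rises and 10 largest falls that passed, and up to 4 members per list. There are 20 gene lists and 3 lists of cell type markers, with 455 members of which 454 were measured. List shifts were tested with cameraPR at a preset correlation of 0.01 and again with the correlation estimated, adjusted over the lists. In WT after 1 h, the median change was 0.13 for peroxide and superoxide scavenging, 0.87 for heat shock proteins, 0.18 for heat shock factors, 0.06 for DNA damage, 0.04 for the cell cycle, 0.02 for stress factors, -0.05 for mitochondrial markers, -0.09 for glutathione transferases, -0.33 for sulfate assimilation, 0.20 for light harvesting, 0.21 for photoprotection and 0.21 for flavonoids. It was 0.16 for photorespiration, -0.09 for salicylic acid, -0.03 for jasmonate, 0.13 for abscisic acid, -0.18 for auxin, 0.43 for the unfolded protein response, 0.09 for the clock and -0.41 for senescence. The marker medians were 0.29 for guard cells, 0.07 for vascular tissue and 0.00 for floral organs.

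The model fits and the list test were tried on simulated normalized values, the fits with 24529 genes in 5 runs per comparison. Background correction, normalization, probe choice and the filter were not part of the simulation. For the cat2 response the fit recovered 80.0% of genes changed 1.5-fold, 98.2% at 2-fold and 99.7% at 4-fold. The cat2 minus WT response gave 27.8%, 91.6% and 99.7%, cat2 against WT at 0 h 8.96%, 80.0% and 99.7%, and at 1 h 45.1%, 97.6% and 100%. Departure from additivity gave 0.597%, 22.4% and 97.6%. False calls made up 5.61%, 6.90%, 7.39%, 6.91% and 8.90% of the calls of these 5 comparisons in that order, so somewhat above the nominal 5%. A list of 30 genes raised 1.5-fold was found in 100% of 20 runs, and unchanged lists were called in 1.5%. The simulated noise was independent between genes and arrays, and every genotype followed the same dye and replicate term. The real data depart from both settings. Each simulated run also changed fewer genes than the real comparison called. These rates therefore need not hold for the real data. Of 112 real list shifts at the preset correlation, 46 were lost with an estimated correlation.

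Alternatives tried were Feature Extraction processed signals, median centring in place of loess, no filter, a filter on all 16 channels, no dye and replicate term, a joint fit of all 16 channels, every probe on its own, the deposited log ratios, quantile normalization, and leaving out each array in turn.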

Results

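The arrays compare leaf RNA taken after 1 h of high light with leaf RNA taken at 0 h, in wild type (WT), in mutants of cytosolic ascorbate peroxidase 1 (apx1) and of catalase 2 (cat2), and in the double mutant apx1/cat2. Each genotype has 2 arrays from 2 independent experiments. Every log2 change below is the mean of those 2 arrays with its standard error (SE) and an adjusted p from limma with Benjamini-Hochberg correction, and a gene is said to have risen or fallen only where that adjusted p is under 0.05. Plant age differs with genotype, so a genotype difference is also a difference in age.

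The targeted genes came first. APX1, which encodes the cytosolic enzyme that reduces hydrogen peroxide with ascorbate, was lower in apx1 than in WT by log2 -5.88 at 0 h (SE 0.18, adjusted p = 0.000241) and by -7.15 at 1 h (SE 0.16). In apx1/cat2 the APX1 signal was lower by -5.11 at 0 h and by -5.11 at 1 h. CAT2, the main leaf peroxisomal catalase, was lower in cat2 by -4.42 at 0 h (SE 0.20, adjusted p = 0.000213) and by -5.31 at 1 h (SE 0.51), and in apx1/cat2 by -5.12 and -5.41. The signals of both genes were on the labelled side in all 16 channels. APX1 was higher in cat2 than in WT, by 1.49 at 0 h (SE 0.18, adjusted p = 0.00785). High light raised APX1 in WT (1.34, SE 0.13, adjusted p = 0.00253). It rose in cat2 as well (adjusted p = 0.0313), where 1 of the 2 signals at 1 h is saturated, so that no size is given. The small remaining APX1 signal also rose in apx1/cat2 (1.33, SE 0.13, adjusted p = 0.00349), while in apx1 its change was 0.06 (adjusted p = 0.791). CAT2 passed in none of the 4 light responses, with adjusted p from 0.578 in WT to 0.885 in apx1/cat2. CAT2 in cat2 moved in opposite ways on the 2 arrays, by 0.85 and -1.66. That scatter enters the spread shared by all 4 genotypes, so it also weakens the CAT2 tests in the other genotypes.

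**Figure D1:**
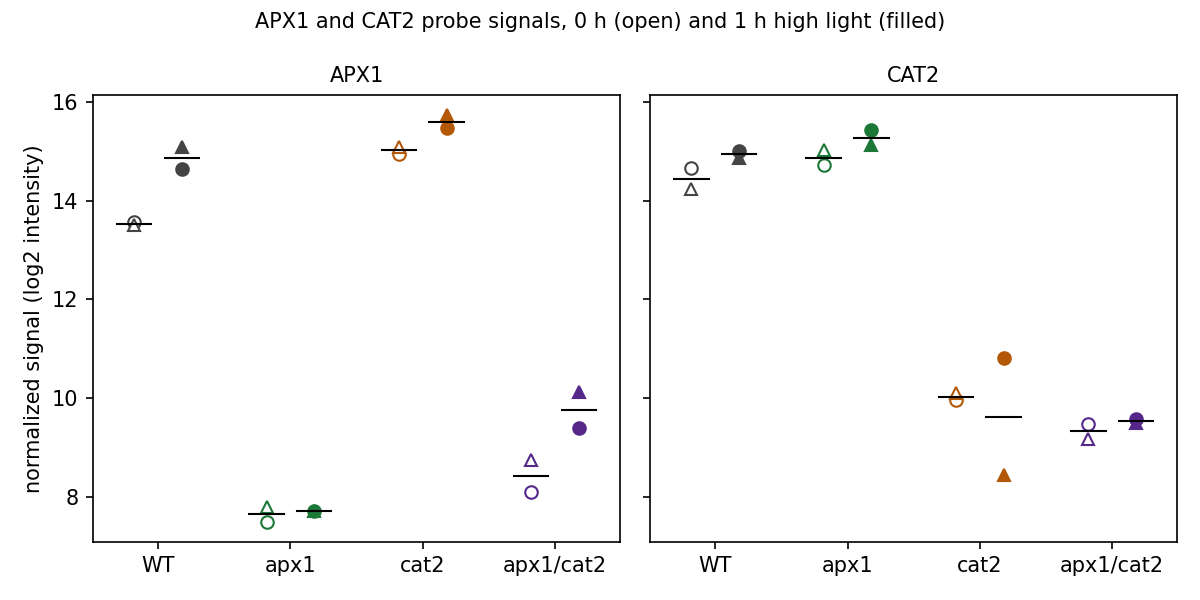
Normalized APX1 and CAT2 probe signals (log2 intensity, vertical axis) in each genotype at 0 h (open) and after 1 h of high light (filled), with circles and triangles for replicates 1 and 2 and a line at their mean. At 0 h APX1 in apx1 lies -5.88 from WT and CAT2 in cat2 lies -4.42 from WT.

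In WT leaves, 1 h of high light raised 1745 of 24529 loci and lowered 1864, 295 and 445 of them by at least 2-fold. The largest rise was GPT2, a glucose 6-phosphate/phosphate translocator induced by light acclimation (log2 4.50, SE 0.14, 22.6-fold). AT1G07400, a class I small heat shock protein, rose by 3.94 (SE 0.13), the purple acid phosphatase PAP17 by 3.45 (SE 0.11), the BTB-domain gene BT1 by 3.41, HSP70 by 3.40 and the glycerophosphodiester phosphodiesterase gene SRG3 by 3.37 (SE 0.07). HSFA2, the heat shock factor that prolongs acquired tolerance, rose by 3.23 (SE 0.17), and the B-box gene BBX31 by 3.16. The largest falls were the ethylene response factor gene AT5G61590 (-4.42, SE 0.19), the kelch F-box gene AT1G80440 (-4.31), the zinc finger gene ATCTH (-4.12), the kelch F-box gene AT1G23390 (-4.08), RAV2 (-3.76), the trehalose phosphate synthase-like gene TPS8 (-3.72) and the J-domain gene J8 (-3.60).

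Among the lists fixed before the data were examined, the anthocyanin and senescence lists kept their shift in WT under an estimated correlation between genes. Of 28 flavonoid and anthocyanin genes, 11 rose and 1 fell (13 and 2 when adjusted over the list alone). The light-signalling factors HY5 (1.85, SE 0.11) and HYH (1.65), the anthocyanin regulator PAP1 (1.85, SE 0.18) and the flavonol glucosyltransferase UGT78D2 (1.52) led it, and the list median was 0.29 on each array (adjusted p = 0.0127 with an estimated correlation). Of 8 senescence genes, 4 fell and 0 rose, led by the NAC regulators NAP (-3.52, SE 0.07) and NAC6 (-2.63, SE 0.25) and by SEN1 (-1.25), with adjusted p = 5.2e-05 with an estimated correlation. Of 28 heat shock proteins and co-chaperones, 14 rose and 0 fell (16 over the list alone), with array medians of 0.98 and 0.69. That shift had adjusted p = 2.2e-15 with a preset correlation of 0.01 and 0.195 with an estimated correlation. Of 13 unfolded protein response genes 6 rose, such as the lumenal chaperones BIP2 (1.57) and BIP1 (1.48), and 8 over the list alone (adjusted p = 0.00169, 0.468 with an estimated correlation). Of 19 abscisic acid, cold and dehydration genes, 4 rose, LTI78 by 2.14, ERD10 by 1.37, RD20 by 1.29 and HAB1 by 0.31 (adjusted p = 0.0139, 0.195 with an estimated correlation). Of 13 heat shock factors, 5 rose and 2 fell (adjusted p = 0.0253, 0.223 with an estimated correlation). The early light-induced genes ELIP1 and ELIP2, which bind pigments under photostress, rose by 1.08 and 1.00. Clock genes moved both ways, GI by 2.04, PRR9 by 1.11, RVE1 by -1.95 and LHY by -1.07. The ethylene factors ERF2 (-1.77) and ERF-1 (-1.56) and the sulfur-deficiency gene ATSDI1 (-3.11, SE 0.63) fell.

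The apx1 response followed the WT response closely. SRG3 rose by 4.19 (SE 0.07), GPT2 by 4.15, AT1G07400 by 4.12, the FKBP-type isomerase gene AT5G48570 by 3.68, PAP17 by 3.60, HSFA2 by 3.41, the HSP70/HSP90 organizing gene Hop3 by 3.31 and the phosphate sensor SPX1 by 3.02. AT5G61590 (-4.34), AT1G80440 (-4.21), J8 (-3.88), ATCTH (-3.82) and NAP (-3.68) had the largest falls, followed by the ethylene factor gene ESE3 (-3.48). Of 24527 loci, 2951 rose and 2453 fell. Of 28 heat shock proteins, 16 rose (17 over the list alone, adjusted p = 0.243 with an estimated correlation). Of 13 unfolded protein response genes, 10 rose, with BIP2 at 1.95 and BIP1 at 1.91 (11 over the list alone, adjusted p = 0.401 with an estimated correlation). Of 18 photoprotection genes, 6 rose and 1 fell, and of 43 scavenging genes 7 rose and 1 fell, with the monodehydroascorbate reductase ATMDAR2 at 0.74 and the copper/zinc superoxide dismutase CSD1 at -0.70. Senescence genes again fell, 4 of 8 with 1 rise (adjusted p = 0.000419 with an estimated correlation).

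No gene passed for a difference between the apx1 and WT light responses by limma. The smallest adjusted p was 0.0826, and 1149 loci had an unadjusted p under 0.05. The count was 0 again in the fits on Feature Extraction processed signals and on the deposited log ratios, and 41 in a joint fit of all 16 channels. APX1 differed by -1.27 (SE 0.18, adjusted p = 0.375). The sulfur genes ATSDI1 (2.57, SE 0.90, adjusted p = 0.948) and APR3 (1.74, SE 0.32, adjusted p = 0.537) had the largest differences of their list, of which 2 members passed over the list alone (list adjusted p = 0.0045, 0.829 with an estimated correlation). The flavonoid list lay lower in apx1, with a median of -0.11 (adjusted p = 0.000183, 0.307 with an estimated correlation). PAP1 differed by -0.86 (adjusted p = 0.931).

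In cat2 the same hour of light raised a broad set of stress regulators. SRG3 rose by 5.31 (SE 0.07), the dehydration-responsive factor gene AT1G22810 by 4.96 (SE 0.19), the zinc finger repressor STZ (ZAT10) by 4.93 (SE 0.10), the small heat shock protein AT1G54050 by 4.89 (SE 0.32) and the calcium-binding gene AT3G29000 by 4.84. The indole glucosinolate genes CYP81F2 and IGMT2 rose by 4.75 and 4.63, and the heat and drought regulator DREB2A by 4.60 (SE 0.16). AT5G57760 had the largest fall (-3.12, SE 0.20), followed by genes such as the expansin EXPA8 (-2.59) and the auxin-induced SAUR63 (-2.56), AT1G29500 (-2.33), SAUR29 (-2.27) and AT1G29460 (-2.25). Of the 10 genes of the auxin list, 4 fell and 1 rose, and the list did not pass (adjusted p = 0.112, 0.542 with an estimated correlation). In all, 2759 loci rose and 1346 fell, and 1151 of the rises and 178 of the falls were of at least 2-fold.

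Of 28 heat shock proteins and co-chaperones 26 rose (28 over the list alone), with array medians of 3.56 and 3.18, and with the coactivator MBF1C at 4.21, AT1G59860 at 4.02 and AT5G51440 at 3.85 (adjusted p = 0.000193 with an estimated correlation). Of 37 stress-responsive transcription factors, 31 rose and 0 fell, such as ZAT6 (4.32, SE 0.08) and WRKY40 (4.26, SE 0.11). Of 13 heat shock factors, 10 rose, with HSFA2 at 4.36 and HSF A4A at 3.35. Glutathione transferases rose in 12 of 15 cases, GSTF6 by 3.78 and GSTF7 by 3.51. Of 13 mitochondrial dysfunction and oxidative stress markers 8 rose, among them CYP81D8 (3.86), SAG21 (3.15), the AAA-ATPase gene BCS1 (2.92) and the alternative oxidase AOX1A (2.01). Sulfate assimilation rose in 11 of 18 genes and fell in 1, with the adenylyl-sulfate reductases APR3 at 3.08 and APR1 at 3.07 (adjusted p = 0.0384 with an estimated correlation). Of 19 salicylic acid and pathogen genes, 13 rose, with GRX480 at 3.82 and the camalexin gene PAD3 at 3.40 (adjusted p = 0.0173 with an estimated correlation), and of 19 abscisic acid genes 9 rose, with ABI2 at 1.86 and NCED3 at 1.69 (adjusted p = 0.01 with an estimated correlation). Jasmonate genes rose in 8 of 27 cases and fell in 1, led by OPR3 (2.73) and LOX3 (2.22), with adjusted p = 0.00244 and 0.357 with an estimated correlation. The dehydroascorbate reductase DHAR2 rose by 2.82 (SE 0.11) and APX2, a heat-inducible cytosolic ascorbate peroxidase, by 0.97. In the flavonoid list 5 genes rose and 6 fell, HY5 by 1.32 and chalcone synthase TT4 by -1.29. Its mean of -0.02 and its test pointed down while its median was 0.04 (adjusted p = 0.54). Cell cycle genes shifted down with 4 of 31 falling (adjusted p = 0.0495, 0.343 with an estimated correlation).

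**Figure D2:**
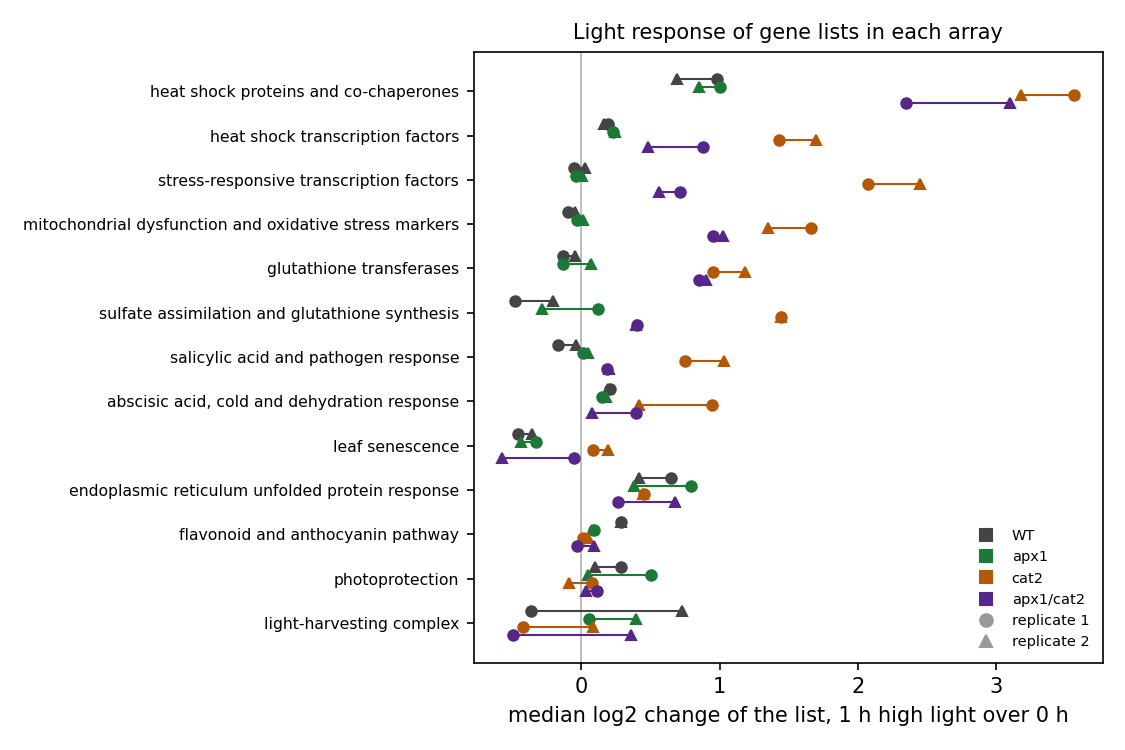
Median log2 change of gene lists after 1 h of high light (horizontal axis), with 1 point per array, a line joining the 2 arrays of a genotype, and colours for the genotypes. Heat shock proteins have medians of 3.56 and 3.18 in cat2, 2.35 and 3.10 in apx1/cat2, and 0.98 and 0.69 in WT.

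Tested directly, the light response differed between cat2 and WT for 3351 loci, 2384 of them higher in cat2 and 967 lower. Sulfur-deficiency genes stood out, as ATSDI1 differed by 5.94 (SE 0.90), LSU3 by 5.70 (SE 0.54), LSU1 by 4.50 and APR1 by 3.92. The protease inhibitor gene AT1G17860 differed by 5.89, IGMT2 by 5.58, CYP81F2 by 5.42, RAV2 by 5.11 and the nematode-resistance relative HSPRO2 by 5.10. Lower in cat2 were the cysteine protease genes AT2G27420 (-2.75) and AT3G49340 (-2.69), the acetyltransferase-like gene TBL26 (-2.65), GPT2 (-2.57, SE 0.20) and the starch synthase GBSS1 (-2.42). Of 37 stress factors, 30 differed upwards, DREB2A by 4.40, ERF104 by 4.25 and ZAT11 by 4.18, and of 28 heat shock proteins 18 did so, with AT5G37670 at 3.47 and Hsp70b at 3.27 (adjusted p = 0.0494 with an estimated correlation). Of 15 glutathione transferases, 10 were higher, and of 18 sulfate genes 11 were higher and 1 lower (adjusted p = 0.0202 with an estimated correlation). Flavonoid genes were lower in 12 of 28 cases and higher in 1 (15 and 1 over the list alone), such as 4CL3 (-1.67), PAP1 (-1.53) and TT4 (-1.19), with adjusted p = 0.0444 with an estimated correlation. Senescence genes were higher in 5 of 8 cases, NAP by 3.16 (SE 0.11) and SAG13 by 2.67 (adjusted p = 0.000666 with an estimated correlation).

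Heat shock proteins rose in the double mutant too. SRG3 rose by 5.22 (SE 0.07), AT1G07400 by 4.57, AT1G59860 by 4.21, the disease-resistance gene AT1G66090 by 4.09, Hop3 by 3.99, HSFA2 by 3.86 and SPX1 by 3.79. ATCTH fell by 2.97, and ESE3 (-2.60), the B-box gene BBX14 (-2.33) and TPS8 (-2.22) followed. In all, 1348 loci rose and 612 fell. Of 28 heat shock proteins, 25 rose (27 over the list alone), with array medians of 2.35 and 3.10 (adjusted p = 1.1e-06 with an estimated correlation). In a contrast with the cat2 response that was added later, 4 of the 28 were lower and 0 higher, with a median of -0.73 (adjusted p = 1.8e-07, 0.303 with an estimated correlation). In that contrast 4 of 13 heat shock factors were lower and 0 higher, with a median of -0.48 (adjusted p = 4.4e-05 with an estimated correlation). Of 37 stress factors 19 were lower, with a median of -0.88 (cameraPR adjusted p = 5.9e-41, 2.1e-46 with an estimated correlation). Here the estimated correlation gave the laxer test, and p values this small from 2 arrays per genotype should not be read literally. Of 37 stress factors 22 rose, with ZAT6 at 3.05, STZ at 3.01, DREB2A at 2.89 and WRKY40 at 2.85, and 8 of 15 glutathione transferases rose, with GSTF6 at 1.64. Sulfate genes rose in 4 of 18 cases, APR3 by 2.74 (adjusted p = 1.5e-05, 0.0825 with an estimated correlation), and in the salicylic acid list GRX480 alone passed (2.64), with 5 over the list alone (adjusted p = 0.000505, 0.1 with an estimated correlation). Senescence genes fell in 3 of 8 cases, as NAP fell by 1.58 and SEN1 by 1.32 (adjusted p = 0.0171 with an estimated correlation). Flavonoid genes rose in 7 cases and fell in 2, HY5 by 1.96 (adjusted p = 0.0271, 0.286 with an estimated correlation).

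Against the WT response, 819 loci differed in apx1/cat2, 631 upwards and 188 downwards. LSU3 differed by 4.21 (SE 0.54), AT1G66090 by 3.79, the purine permease PUP18 by 3.76, IGMT2 by 3.57 and APR3 by 3.29. Lower were AT4G34950 (-2.70), TBL26 (-2.21), GPT2 (-2.09), GBSS1 (-2.05) and the drought gene RD20 (-1.67). Stress factors differed upwards in 16 of 37 cases (24 over the list alone), with WRKY40 at 2.81 and ZAT6 at 2.67, and heat shock proteins in 11 of 28 (20 over the list alone), with AT1G53540 at 3.29 (adjusted p = 0.044 with an estimated correlation). Sulfate genes were higher in 6 of 18 cases (adjusted p = 0.016 with an estimated correlation). F3H (-0.90) and UF3GT (-0.88) were the flavonoid genes that passed, both lower (list adjusted p = 0.000142, 0.0627 with an estimated correlation). GRX480 (2.32) and NIMIN1 (1.03) passed in the salicylic acid list (adjusted p = 3.5e-05, 0.0504 with an estimated correlation).

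**Figure D3:**
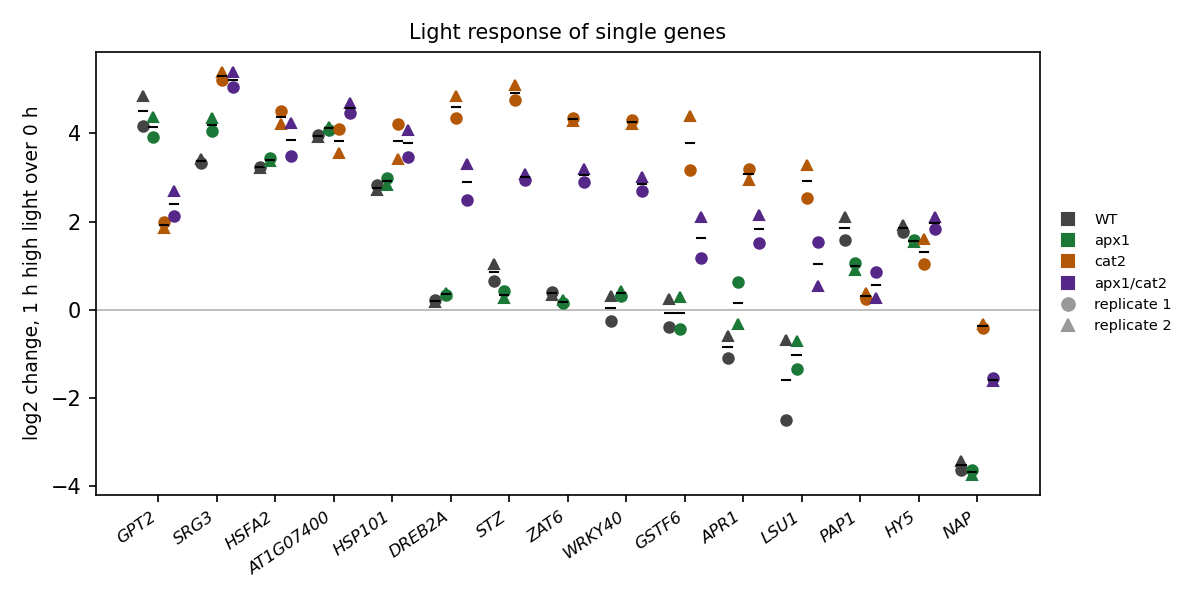
Log2 change after 1 h of high light (vertical axis) of 15 named genes, with 1 point per array, colours for the genotypes and a line at the mean of the 2 arrays. DREB2A rises by 4.60 in cat2 and 2.89 in apx1/cat2, while NAP falls by 3.52 in WT and by 3.68 in apx1.

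Across genes, which are not independent replicates, the WT and apx1 responses correlated with r = 0.904, WT and cat2 with 0.199, WT and apx1/cat2 with 0.518, and cat2 and apx1/cat2 with 0.804. Of the loci that rose, 1468 did so in both WT and apx1, against 210 if the lists were independent, and 1130 in both cat2 and apx1/cat2, against 152. WT and cat2 shared 597 rises and 508 falls, and 365 loci passed in opposite directions, such as RAV2 (-3.76 in WT and 1.35 in cat2). WT and apx1 had 3 such loci, and cat2 and apx1/cat2 had 12. No array was shared between these responses.

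Before high light, apx1 and WT differed at 181 loci, 92 higher and 89 lower in apx1. The epithiospecifier ESP was higher by 3.80 (SE 0.28) and the myrosinase TGG2 by 3.43 (SE 0.15), while the specifier modifier ESM1 was lower by -4.59 (SE 0.23). AT4G16215 (5.25), the bromodomain gene AT1G58025 (4.89) and ECS1 (4.37) were higher, and the thionin gene AT1G66100 (-4.18), the defensin PDF1.2 (-3.71), the histone methyltransferase SUVH3 (-3.51) and PIFI (-3.23) were lower. For the resistance gene AT1G63880, below background in apx1, the difference was at least 7.27-fold. BGL2, a pathogenesis-related glucanase, was higher by 1.87 and the sulfurylase APS4 by 2.42. No heat shock protein, heat shock factor or DNA damage gene passed. The senescence list lay higher with SAG29 at 1.85 (adjusted p = 0.000689 with an estimated correlation) and the vascular list lower with SWEET12 at -0.99 (adjusted p = 0.0398 with an estimated correlation). The shifts of 4 other lists (jasmonate 0.0961, auxin 0.212, abscisic acid 0.25, salicylic acid 0.875) were lost with an estimated correlation. Of 10 auxin genes, 5 were lower over the list alone, SHY2 by -1.34 (adjusted p = 0.0896 over all loci). In the scavenging list APX1 itself was the 1 member that passed (adjusted p = 0.00963 with an estimated correlation), and without APX1, CAT2 and CAT3 the list had adjusted p = 0.894 with an estimated correlation.

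In cat2 at 0 h, 444 loci were higher and 591 lower than in WT. That balance turned with processed signals (230 higher, 172 lower) and with quantile normalization (524 and 450). AT4G16215 was higher by 6.53, the glucosyltransferase UGT74E2 by 6.46 (SE 0.20), AT1G58025 by 6.18, the glutathione transferase GSTU24 by 5.96 and the cytochrome P450 CYP81D11 by 5.51. TGG2 (4.95), the glutathione transferase GSTU1 (4.56) and ESP (saturated in cat2, at least 21.6-fold) were higher as well. ESM1 (-5.60), the brighter CAT3 probe (-4.73, SE 0.26), the isopropylmalate synthase relative IMS2 (-4.26), AT1G66100 (-4.01) and SUVH3 (-3.52) were lower. Heat shock proteins were higher without high light in 15 of 28 cases (19 over the list alone), such as AT1G53540 (4.48) and AT1G07400 (3.67), with array medians of 1.15 and 1.42 (adjusted p = 1.6e-12 with an estimated correlation). HSFA2 was higher by 2.00, the NAC factors NAC032 by 2.41 and NAC102 by 2.25, and ELIP2 by 3.16 (photoprotection list adjusted p = 0.0015 with an estimated correlation). Of 28 flavonoid genes, 2 were higher and 1 lower (adjusted p = 0.00769 with an estimated correlation). The scavenging list had 3 genes higher, APX1 among them, and 2 lower, which are CAT2 and CAT3. Without APX1, CAT2 and CAT3 it did not pass (adjusted p = 0.587, 0.672 with an estimated correlation). The cold genes COR15A (-2.59) and KIN2 (-2.18), the jasmonate enzyme AOS (-2.29) and BGL2 (-2.19) were lower. The jasmonate list (adjusted p = 0.00488, 0.133 with an estimated correlation) and the stress factor list (0.0013, 0.181 with an estimated correlation) had members on both sides.

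The double mutant differed most before high light, with 832 loci higher and 1148 lower than in WT, a balance that turned with processed signals (384 higher, 309 lower). The cysteine oxidase gene AT5G15120 was below background in WT and at least 46.3-fold higher in apx1/cat2. The ribosomal protein gene RPS15AD was higher by 5.22 (SE 0.15), the resistance homologue HR4 by 5.20, AT4G01870 by 4.97, the AAA-type ATPase gene AT3G28540 by 4.88, GSTU24 by 4.82, LBD41 by 4.68 and the metal transporter NRAMP3 by 4.59. The brighter CAT3 probe (-4.16), IMS2 (-3.44), COR15A (-3.00) and IGMT2 (-2.80) were lower. DNA damage genes were higher in 16 of 38 cases with 0 lower (21 over the list alone), and the array medians were 0.75 and 0.46 (adjusted p = 0.00426 with an estimated correlation). AT3G27630 was higher by 3.06 (SE 0.26), the poly(ADP-ribose) polymerase PARP2 by 2.69 (SE 0.28), AT1G07500, a SIAMESE-related cell cycle inhibitor, by 2.59 (SE 0.26) and the repair gene BRCA1 by 2.34 (SE 0.19). In the cell cycle list the inhibitors KRP6 and LGO were higher, by 1.42 and 1.15, while KRP2 was lower by -0.78.

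Heat shock proteins in apx1/cat2 at 0 h were higher in 8 of 28 cases and lower in 2, with AT1G53540 at 2.51 (adjusted p = 8.4e-05, 0.065 with an estimated correlation). ELIP2 was higher by 4.33 (SE 0.17) and ELIP1 by 2.18 (photoprotection adjusted p = 0.00995 with an estimated correlation), UGT74E2 by 3.88 and GSTU1 by 3.51. Scavenging genes were lower in 9 of 43 cases and higher in 5, ATMDAR2 by 2.14. The 9 include APX1, CAT2 and CAT3, without which the list had adjusted p = 0.656 with an estimated correlation. Of 28 flavonoid genes 4 were higher, PAL1 by 1.52 (adjusted p = 0.0123 with an estimated correlation). Jasmonate genes were lower in 6 of 27 cases, PDF1.2 by -2.15 and VSP2 by -1.69 (adjusted p = 0.0149, 0.173 with an estimated correlation), and sulfate genes in 3 of 18, APS3 by -1.52 (adjusted p = 0.0293, 0.159 with an estimated correlation). The alcohol dehydrogenase ADH1 was higher by 2.04 (SE 0.13).

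**Figure D4:**
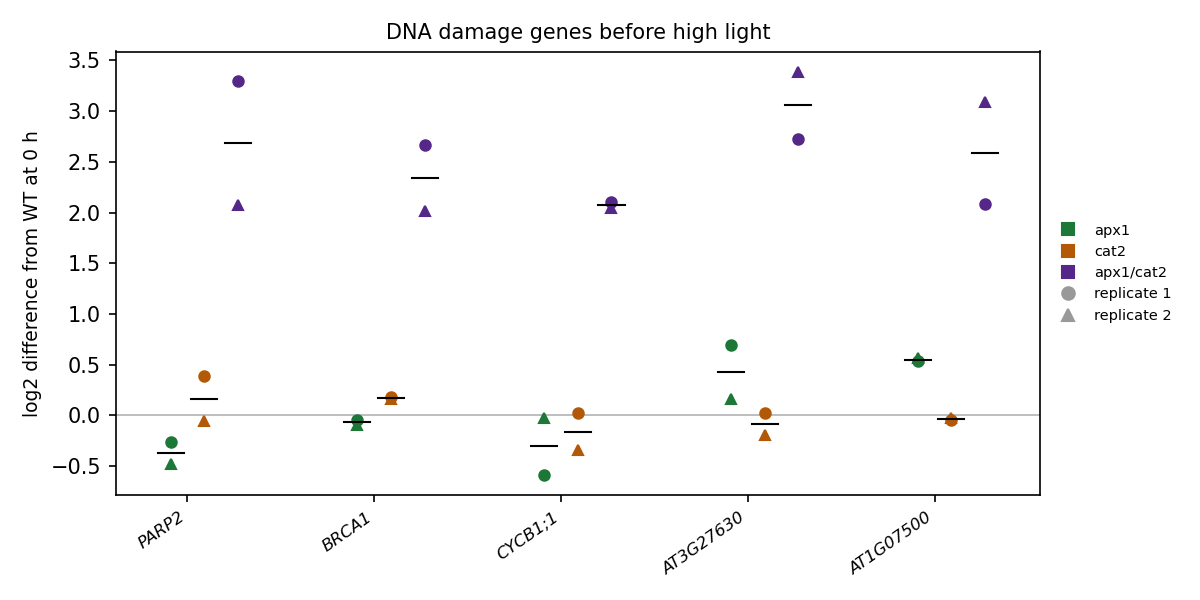
Log2 difference from WT at 0 h (vertical axis) of 5 DNA damage genes in apx1, cat2 and apx1/cat2, each point being 1 array minus the WT array of the same replicate and each line the mean. In apx1/cat2 the means run from 2.08 for CYCB1;1 to 3.06 for AT3G27630.

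Departure from additivity compares the double mutant with the sum of the 2 single-mutant differences at 0 h, and 509 loci passed, 273 above the sum and 236 below. Of 38 DNA damage genes 8 lay above the sum and 0 below (19 over the list alone), with PARP2 at 2.89 (SE 0.39), AT3G27630 at 2.71, the mitotic cyclin CYCB1;1 at 2.55 and BRCA1 at 2.24 (adjusted p = 0.0302 with an estimated correlation). Heat shock proteins lay below the sum in 6 of 28 cases (11 over the list alone), AT5G48570 by -2.16, AT1G07400 by -2.11 and HSP101 by -1.90, with array medians of -0.67 and -0.83 (adjusted p = 0.00282 with an estimated correlation). CYP81D8 (-2.73) and UGT74E2 (-2.18) also lay below and AT2G21640 above (1.44, adjusted p = 0.0307; mitochondrial list adjusted p = 0.00515, 0.0816 with an estimated correlation), as did GSTU8 (2.19). Most of the largest departures belonged to genes that differed from WT in both single mutants and not in the double, as ESM1 (10.63, SE 0.33), SUVH3 (7.81) and PIFI (6.95) above the sum, and AT4G16215 (-11.52), AT1G58025 (-10.96), TGG2 (-8.60) and ESP (saturated in cat2) below it. AT1G66100 (9.21) was lower in both single mutants and higher in the double (1.02, adjusted p = 0.0486). SAG29 lay below by -4.16 (senescence list adjusted p = 0.0222 with an estimated correlation).

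**Figure D5:**
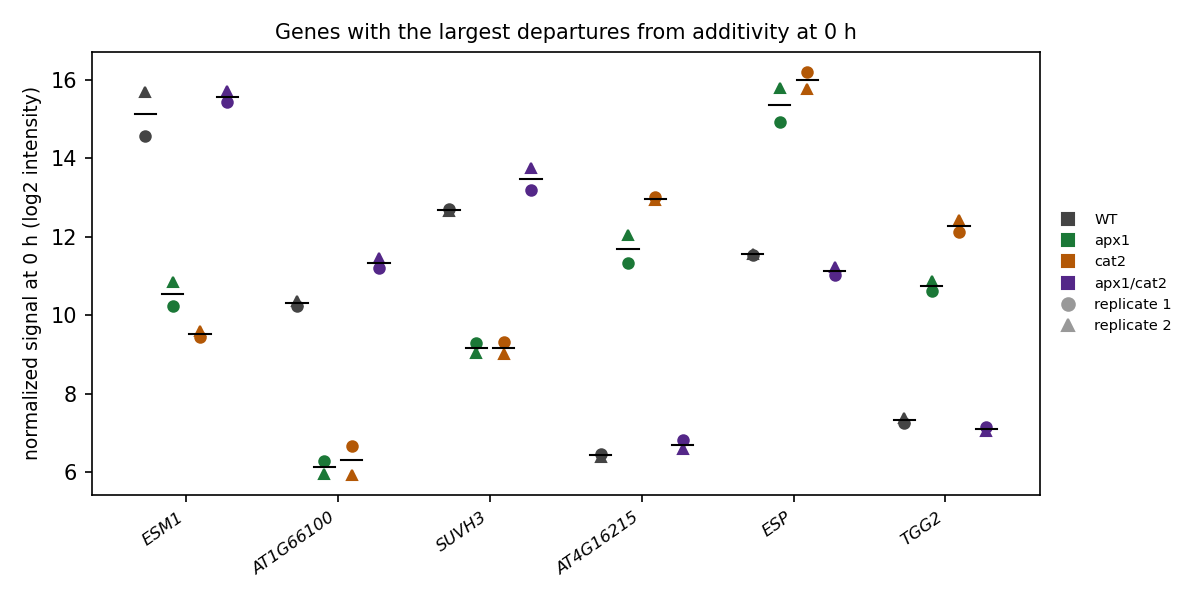
Normalized probe signals at 0 h (log2 intensity, vertical axis) of 6 of the genes with the largest departures from additivity, with 1 point per array, colours for the genotypes and a line at the mean. ESM1 lies -4.59 from WT in apx1 and -5.60 in cat2, and its departure is 10.63. ESP is saturated in cat2.

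After 1 h of high light, apx1 and WT differed at 547 loci upwards and 448 downwards. The scavengers CSD2 (-1.86, SE 0.18) and GPX7 (-1.40) were lower in apx1 and ATMDAR2 higher (1.12), with 4 of 43 scavenging genes lower, APX1 included, and 1 higher (adjusted p = 0.00925, 0.0861 with an estimated correlation). Without APX1, CAT2 and CAT3 the list had adjusted p = 0.71, and 0.779 with an estimated correlation. The stress factors STZ (-1.27), ERF-1 (-1.09) and ERF5 (-0.98) were lower, as were PAP1 (-1.15) and PAL1 (-0.89) of the flavonoid list (adjusted p = 0.00731, 0.147 with an estimated correlation). The salicylic acid genes BGL2 (2.04) and WAK1 (1.16) were higher (adjusted p = 0.00925, 0.121 with an estimated correlation), and so was SAG29 (2.29; senescence list adjusted p = 0.00731, 0.0668 with an estimated correlation). LTI78 was higher by 1.12 and SHY2 lower by -1.25 (abscisic acid list 0.121, auxin list 0.15 with an estimated correlation). No heat shock protein passed, and AT5G48570, at 0.82, had adjusted p = 0.0895.

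In cat2 at 1 h, 3339 loci were higher and 3405 lower than in WT. UGT74E2 was higher by 7.95 (SE 0.10), AT1G53540 by 7.68, CYP81D11 by 7.54, GSTU24 by 7.52, CYP81D8 by 6.60 and the glucosyltransferase UGT73B3 by 6.59. Of 28 heat shock proteins 27 were higher, with array medians of 3.29 and 3.55 (adjusted p = 0.00731 with an estimated correlation). Stress factors were higher in 29 of 37 cases and lower in 2, WRKY40 by 5.68 and DREB2A by 5.08, and glutathione transferases in 12 of 15. Salicylic acid genes were higher in 11 of 19 cases and lower in 1, PAD3 by 4.24 (adjusted p = 0.0109 with an estimated correlation), and sulfate genes in 10 of 18 with 2 lower, APR3 by 4.65 (adjusted p = 0.0149 with an estimated correlation). Senescence genes were higher in 5 of 8 cases, NAP by 2.50 (adjusted p = 0.00731 with an estimated correlation). PAP1 was lower by -2.25, COR15A by -2.47 and SHY2 by -2.04, while RVE1 was higher by 1.73.

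In apx1/cat2 at 1 h, 2909 loci were higher and 3162 lower. GSTU24 (6.26, SE 0.16), UGT74E2 (6.07), AT1G53540 (5.80) and AT4G01870 (5.72) led, and HR4, AT5G15120 and LBD41, all below background in WT, were at least 63.1-fold, 39.7-fold and 38.5-fold higher. DNA damage genes were higher in 19 of 38 cases and lower in 1, AT3G27630 by 2.89, AT1G07500 by 2.77 and PARP2 by 2.73 (adjusted p = 1.8e-05 with an estimated correlation). Heat shock proteins were higher in 21 of 28 cases and lower in 1, with Hsp70b at 3.60 (adjusted p = 3.7e-13, 0.129 with an estimated correlation). Stress factors were higher in 26 of 37 cases and lower in 1, salicylic acid genes in 13 of 19 with GRX480 at 3.01 (adjusted p = 0.0024 with an estimated correlation), and sulfate genes in 7 with 2 lower (adjusted p = 6.3e-05, 0.237 with an estimated correlation). ELIP2 was higher by 4.58 and ELIP1 by 2.40 (photoprotection adjusted p = 0.0498 with an estimated correlation). Scavenging genes were lower in 17 of 43 cases and higher in 5. Without APX1, CAT2 and CAT3, 14 of 40 were lower (adjusted p = 0.299, 0.401 with an estimated correlation).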

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

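All the tests of causes in this part were chosen only after the results had been seen. Comparison between genotypes picked out 3351 loci whose light response differs between cat2 and WT, 819 between apx1/cat2 and WT, and 509 that depart from additivity at 0 h. A look at probes left out of the main tests picked out 229 genome-interval probes that changed with light in cat2, 142 up and 87 down of 7224 tested, against 103 in WT, 195 in apx1 and 68 in apx1/cat2. What those intervals transcribe was not analysed here.

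Of the 509 nonadditive loci, 53 changed alike in apx1 and cat2 at 0 h and did not pass in apx1/cat2, and they include 8 of the 10 largest departures above the sum and 7 of the 10 largest below. A wrong genotype label is argued against by APX1 and CAT2, whose signals fall on the labelled side in 16 of 16 channels. The choice of the set at 0 h places it near WT in apx1/cat2, the oldest plants. Direction was counted as that of the change at 0 h, which was down for 28 genes and up for 25. In that direction 49 of 53 differed less from WT in apx1/cat2 at 1 h than in both single mutants, by more than 2 SE. These 1 h values come from the same arrays, and over the set the apx1 differences from WT at 0 h and 1 h correlated with r = 0.976. They are therefore not an independent test. The choice of the set itself selects against a steady change with plant age, so the 1 h values cannot weigh for or against it. Other effects of age stay open and untested. Chromosome segments from another accession may underlie the set, as all 14 members on chromosome 1 lie at 18.0 to 27.5 Mb, all 12 on chromosome 3 at 1.98 to 10.5 Mb and all 5 on chromosome 2 at 13.7 to 15.3 Mb, and 9 of 26 stretches of 5 Mb hold none, against a median of 5 in random draws (permutation p = 0.007). Yet the 19 on chromosome 5 run from 1.34 to 26.0 Mb, and the 3 on chromosome 4 from 9.18 to 16.6 Mb. After thinning to 1 gene per 100 kb, 30 of 46 members have another within 1 Mb, against a median of 29 in random draws (permutation p = 0.444). The draws were matched at 53 loci before thinning and not at 46 after it, so this count cannot weigh for or against segments. Such segments and a shared response of the single mutants cannot be told apart.

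The apx1/cat2 response is smaller than that of cat2, and a contrast added afterwards gives 128 loci higher and 838 lower. WT RNA in the double mutant samples is argued against, since CAT2 reaches at most 2.99% of WT where the fit would need 31.9%, with weights of 0.204 and 0.434 on the 2 arrays. Compression of ratios as the only cause is argued against too, as the slope on the cat2 response is higher by 0.27 for genes shared with WT than for genes called in cat2 alone. Yet the slopes of the shared genes also fall short, at 0.650 and 0.786 on the 2 arrays. The apx1/cat2 responses also spread less than those of WT (standard deviation 0.338 against 0.395). Compression beside another cause thus stays open. Genes that rise in cat2 lie a median of 0.0478 above WT in apx1/cat2 at 0 h, against a median shortfall of 0.49. The first value is set against WT and the shortfall against cat2. The genes were also chosen by their rise in cat2, which can enlarge the shortfall. An earlier rise can therefore be neither sized nor told apart from none here. Plant age stays open.

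The brighter CAT3 probe was lower with CAT2 in both cat2 lines, by -4.73 in cat2 at 0 h. It also moved in opposite ways on the 2 cat2 arrays, by 1.18 and -1.04, as CAT2 did by 0.85 and -1.66, which goes with a probe that reads CAT2 but would also be seen if both genes varied together. The other CAT3 probe changed by -0.35 in cat2, and it is above background in 15 of 16 channels but dim, at 6.94 on the log2 scale in WT. A CAT3 probe that also reads CAT2 transcripts and a true loss of CAT3 cannot be told apart, and probe sequences are not given in the sources used here.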

How the results depend on the processing

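The alternatives to the fits were planned before the data were examined, while the double minus cat2 contrast, 2 added gene lists and the scavenging list without APX1, CAT2 and CAT3 were chosen after seeing the data. No list shift that was repeated changed direction. No named gene did so where it passed in the main fit or in the repeat. A targeted gene that passed in neither fit was counted as held whatever its direction, so its direction was not checked. Some repeats could not have changed direction. The 906 named-gene repeats with every probe again read the main probe of each locus. The 112 list repeats with an estimated correlation kept the main direction. Both kinds are counted in the totals that follow. Of 14423 repeats of named genes, 12701 held, 1709 were weaker and 13 stronger. Of 336 repeats of list shifts, 277 held and 59 were weaker, 46 of those with an estimated correlation.

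The joint fit of all 16 channels moved most counts. The WT response went from 3609 to 5684, the apx1/cat2 response from 1960 to 3371, the cat2 difference from 3351 to 5136 and the apx1/cat2 difference from 819 to 2133, and the apx1 difference from 0 to 41. At 1 h it gave 191 in place of 995 for apx1, 3886 in place of 6744 for cat2 and 2946 in place of 6071 for apx1/cat2. Feature Extraction processed signals gave 454 for the apx1/cat2 response difference, 62 for apx1, 402 for cat2 and 693 for apx1/cat2 at 0 h, 126 for apx1 at 1 h and 171 for nonadditivity. The deposited log ratios gave 459 for the apx1/cat2 difference. The share of higher loci at 0 h went with processed signals from 42.9% to 57.2% in cat2 and from 42.0% to 55.4% in apx1/cat2, and with quantile normalization to 53.8% in cat2. In both it also passed 50% without either WT array. With the joint fit it went from 49.5% to 56.9% in cat2 at 1 h, and with quantile normalization from 53.6% to 48.9% for nonadditivity. The balance of the WT response, of apx1 at 0 h and 1 h and of apx1/cat2 at 1 h turned in some fits too. The cause was not tested.

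With no replicate block the apx1 count at 1 h fell from 995 to 456. The other counts with no replicate block were 3335, 5078, 3899 and 1874 for the 4 responses, 0, 3239 and 819 for their differences, 146, 738 and 1388 at 0 h, 5566 and 4624 at 1 h, and 351 for nonadditivity. The slide as a block was not run, as each slide holds 1 array.

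Leaving out 1 array moved nearly every count, and a genotype then rests on a lone sample that is assumed to vary like the other groups. The WT response ran from 362 without WT replicate 1 to 6005 without an apx1/cat2 array, apx1 from 735 without its replicate 1 to 8379, cat2 from 1497 without its replicate 2 to 5692, and apx1/cat2 from 1173 without a WT array to 2538. The apx1 difference stayed at 0, the cat2 difference ran from 1194 without WT replicate 1 to 5568, and the apx1/cat2 difference from 44 without WT replicate 2 to 3079 without apx1/cat2 replicate 2. At 0 h apx1 ran from 22 without WT replicate 2 to 1152, cat2 from 135 without its replicate 2 to 3438, and apx1/cat2 from 244 without WT replicate 2 to 5373. At 1 h apx1 ran from 105 to 1712, cat2 from 3548 to 7938, and apx1/cat2 from 2734 to 5993. Nonadditivity ran from 75 without cat2 replicate 2 to 2580 without apx1/cat2 replicate 2. Apart from the apx1 difference, each highest count comes without an apx1/cat2 array, whose replicate deviations differ from those of the other genotypes.

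Signal over background limits which loci are tested. Of 24529 loci, 18824 are above background in all 16 channels, and under that filter 833 of 906 results for named genes could be repeated, of which 832 held. Without a filter 25438 loci are tested.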

Other observations

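Both added lists below were written only after the largest changes had been seen, without the genes that prompted them. Before high light, part of a list of low-oxygen genes was higher in apx1/cat2. Of 21 genes known to be induced by low oxygen, 10 were higher than in WT and 0 lower, with FTM1 at 4.13 (SE 0.31), the haemoglobin HB1 at 3.28 (SE 0.23), AT3G10040 at 3.22 (SE 0.16), AT5G39890 at 2.44 and AT3G03270 at 2.26. The other members did not pass in apx1/cat2, and some were flat or on the lower side, as CML38 (-0.52), ERF73 (-0.25) and ACO1 (0.006). The list median was 0.69, and in apx1 0 of the 21 genes passed and in cat2 2 were lower. At 1 h 14 of the 21 were higher in apx1/cat2, and 9 lay above additivity at 0 h.

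Part of a list of phosphate-starvation genes rose after 1 h of light in all 4 genotypes. Of 13 genes, 7 rose in WT, 8 in apx1, 9 in cat2 and 8 in apx1/cat2. In WT the sulfolipid gene SQD2 rose by 1.27 (SE 0.16) and the phosphatase PS2 by 1.32 (SE 0.21). Other members did not rise, as SPX3, IPS1 and NPC4 hardly moved in any genotype (0.07, 0.05 and 0.04 in WT). RNS1 changed by -0.16 in WT without passing. Some loci first written for this list were cut from it, for a reason that was not recorded. SRG3, PAP17 and SPX1 had prompted the list.

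The low-oxygen shift has p = 3.8e-19 in cameraPR with an estimated correlation. Joint loss of APX1 and CAT2 may underlie it, but plant age of 32 days, tissue state and growth conditions of the older plants are explanations that the design leaves open, and no mechanism was tested. Age-matched plants would separate only age from genotype.

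The phosphate shift has p = 0.000686 in WT with an estimated correlation. It may reflect phosphate bound in sugar phosphates when photosynthesis rises within the hour, a hypothesis that metabolite measurements could test. GPT2, a sugar-phosphate carrier, has the largest rise in WT, by 4.50. In cat2, though, GPT2 rose less, by 2.00 and 1.85 on the 2 arrays, while the list median was higher there (0.91 against 0.53 in WT). The list difference between cat2 and WT did not pass (p = 0.342 in cameraPR with an estimated correlation).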
